A study of Mus musculus with 18 samples.

How the data were processed

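Hippocampal RNA of 7 wild-type, 7 AtrxΔE2 and 4 5-ALA-treated AtrxΔE2 mice had been hybridised to 18 single-colour microarrays, 1 per sample. Per the labels' protocols, the authors amplified total RNA to amino allyl RNA, coupled it to a Cy dye and hybridised it to arrays of 23473 probes. Per the file headers, each array was scanned at 3 gains that were related to each other by least squares, and the deposited value of each spot is a median intensity at 635 nm, with the background in a column of its own and no scaling between arrays named. The background intensity deposited beside each spot followed the spot's own brightness (correlation of logs between 0.944 and 0.998) and was not subtracted. A second deposited table holds the authors' normalized intensity per probe, with 25 as the median of every array. The labels do not say how it was made. It could be rebuilt from the spot intensities to within 0.233% for values of at least the median, by subtracting the mean of the blank spots left after trimming 5% at each end, dropping probes within 2 SD of it and scaling to a median of 25, with at most 1 probe per array detected differently. Its scale is therefore linear, its direction that of the scanner values, and it was used as an alternative.

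Spot intensities were corrected with limma's normexp method (offset 50, fitted on all spots), and unusable spots, at most 11 per array, were left out. Spots of a probe were averaged on the log2 scale and arrays were quantile normalized. A probe was tested when it exceeded the 95th percentile of the blank spots on at least 4 arrays, the size of the smallest group; this kept 22540 probes and left out 933. Of these, 84 had an unusable spot on some array and were fitted on the others. Precision is limited by the number of arrays and, for dim probes, by their signal over the blank spots.

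Gene names came from the platform's annotation, which gives 16631 probes 1 symbol, 0 several, and does not list 6842. Symbols were updated through RefSeq genes on GRCm38.p6: 12622 were current, 3947 were replaced through an unambiguous synonym and 62 were not found. The array's genome build is not stated, so no coordinates are given, and the assembly was used only for names and for which genes lie near each other. For gene lists, a gene was represented by its tested probe of highest mean value.

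The arrays were grouped by the labels' genotype and treatment. The array series was read from the arrays' identifiers and entered the model as a covariate. limma 3.58.1 in R 4.3.3 fitted 1 linear model to all 18 arrays, with moderated two-sided tests of AtrxΔE2 minus wild type, 5-ALA minus AtrxΔE2 and 5-ALA minus wild type. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested probes of a comparison. The 34 gene lists (835 genes, 692 measured) were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the lists of a comparison; each was repeated with an estimated correlation. Correlations of effects across probes were compared with permuted group labels within array series. The signs and correlations of comparisons that share arrays were set beside 100 simulations without effects.

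The comparisons, tests, gene lists, alternatives and the rule for named genes were chosen before the data were examined. Named in every comparison were Atrx, the measured Xlr genes, Camk2a, Alas1 and Hmox1; then per comparison the 12 largest called rises and falls, up to 6 called members and the 4 of smallest p of each called list, and genotype calls that the treatment also called.

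The fit was tested on simulated data for the 22540 probes, with 200 changed per comparison. For log2 changes of 0.25, 0.5 and 1, it recovered 76.1%, 97.0% and 100% in the genotype comparison, with 16 unchanged probes called. It recovered 67.2%, 91.0% and 100% in the treatment comparison, with 5 unchanged probes called, and 55.2%, 91.0% and 100% for treated against wild type, with 9. A simulated shifted list was called for the treatment, with 0 of the other lists. The simulated noise was independent between arrays and between genes. Real consecutive arrays of series B were correlated (consensus 0.359), as were genes of some lists, so these rates do not carry over to the real data.

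The alternatives were the model without the array series, with the series as a random block, each series alone, only the groups compared, the replicate number as a block, no background correction, median scaling, cyclic loess, the authors' table, no filter and a filter on all 18 arrays, a trended and robust prior, array quality weights, other thresholds, the mean of a gene's probes, and leaving out each array. Chosen after seeing the data were averaging consecutive arrays of series B in pairs, those pairs as a random block, leaving out 5-ALA arrays 1 and 2 or 3 and 4, the level of the blank spots as a covariate, and permutations of the correlations that keep these pairs together. The fit to averaged pairs held series B only, while the random block kept series A.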

Results

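Gene expression in the mouse hippocampus was measured on 18 single-colour DNA microarrays. They came from 7 wild-type mice, from 7 AtrxΔE2 mice, whose allele carries a deletion in the X-linked chromatin remodeller gene Atrx, and from 4 AtrxΔE2 mice that received 5-aminolevulinic acid (5-ALA), the precursor from which haem is made. 5-ALA was given by mouth at 3 mg per kg each day from postnatal day 30 until day 90. The labels count as many mice as arrays in each group. The arrays' identifiers fell into 2 series. Series A held wild-type arrays 1 to 3 and AtrxΔE2 arrays 1 to 3, and series B held the other 4 of each genotype and every 5-ALA array. Blank spots averaged between 37.1 and 40.7 intensity units in series A and between 55.2 and 63.2 in series B, and the median probe lay 31.5 to 53.7 units above them. Between 87.2% and 96.0% of the 23473 probes exceeded the 95th percentile of an array's blank spots. Of these probes 22540 were tested, 16151 with a gene name, which stood for 15918 genes. The number of arrays limits the precision. All fold changes are on the log2 scale of background-corrected intensity with an offset of 50, which understates the change of dim genes, so folds on the authors' background-subtracted values are given beside some of them.

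The genotype comparison asked which hippocampal transcripts differ between AtrxΔE2 and wild-type mice. Atrx itself fell by 0.40 (SE 0.066; 7 wild-type and 6 AtrxΔE2 arrays, since 1 AtrxΔE2 spot was marked as unusable), at a limma adjusted p of 0.0333. The authors' values put it at 0.503 of wild type. Where the Atrx probe lies relative to the deleted part is not given, so its level does not check the deletion. Xlr3b, an X-linked imprinted gene of the Xlr family, had the largest rise, 1.01 (SE 0.166, n = 7 per genotype, limma adjusted p 0.0281), or 2.93-fold on the authors' values. Its relative Xlr4b rose by 0.20 (SE 0.0312, limma adjusted p 0.0187). The Xlr3 and Xlr4 genes are near-identical copies, so which copy each probe reads is uncertain. Xlr5d, the other measured member, stood at -0.02 and was not called. On the authors' values it lay between 0.8 and 2.6 where detected, against an array median of 25. A change at this level would hardly show.

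Beside the Xlr genes, Plin3, which coats lipid droplets, rose by 0.50 (SE 0.0518, n = 7 per genotype, limma adjusted p 0.00053), and S100a4, a calcium-binding protein gene, rose by 0.34 (limma adjusted p 0.00356). Pisd, which makes phosphatidylethanolamine in mitochondria, the transcriptional regulator gene Prdm16, the hydroxysteroid dehydrogenase gene Akr1c14 and Cmtm8 rose by between 0.29 and 0.15. Etnppl, an astrocyte enzyme that breaks down phosphoethanolamine, showed the largest fall, -0.62 (SE 0.0912, limma adjusted p 0.0106). The copper transporter gene Atp7a fell by 0.31 (SE 0.0198) with the smallest limma adjusted p of the comparison, 1.24e-06. Rit2, a neuronal small GTPase gene, fell by 0.34, Slc22a4, an organic cation transporter gene, fell by 0.15, and Tnfrsf17 fell by 0.07. Camk2a (0.10), Alas1 (0.01) and Hmox1 (-0.02) were not called. In all, limma called 20 probes, 14 higher and 6 lower in AtrxΔE2, and 14 of the 20 carry a gene name. Each of the 20 moved the same way in both series, but they were called from a fit of both series together. This selection largely fixes the shared direction, so it is no independent check. Xlr3b rose by 0.70 in series A and 1.23 in series B, Atrx fell by 0.52 and 0.29, and Atp7a fell by 0.34 and 0.28.

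**Figure D1:**
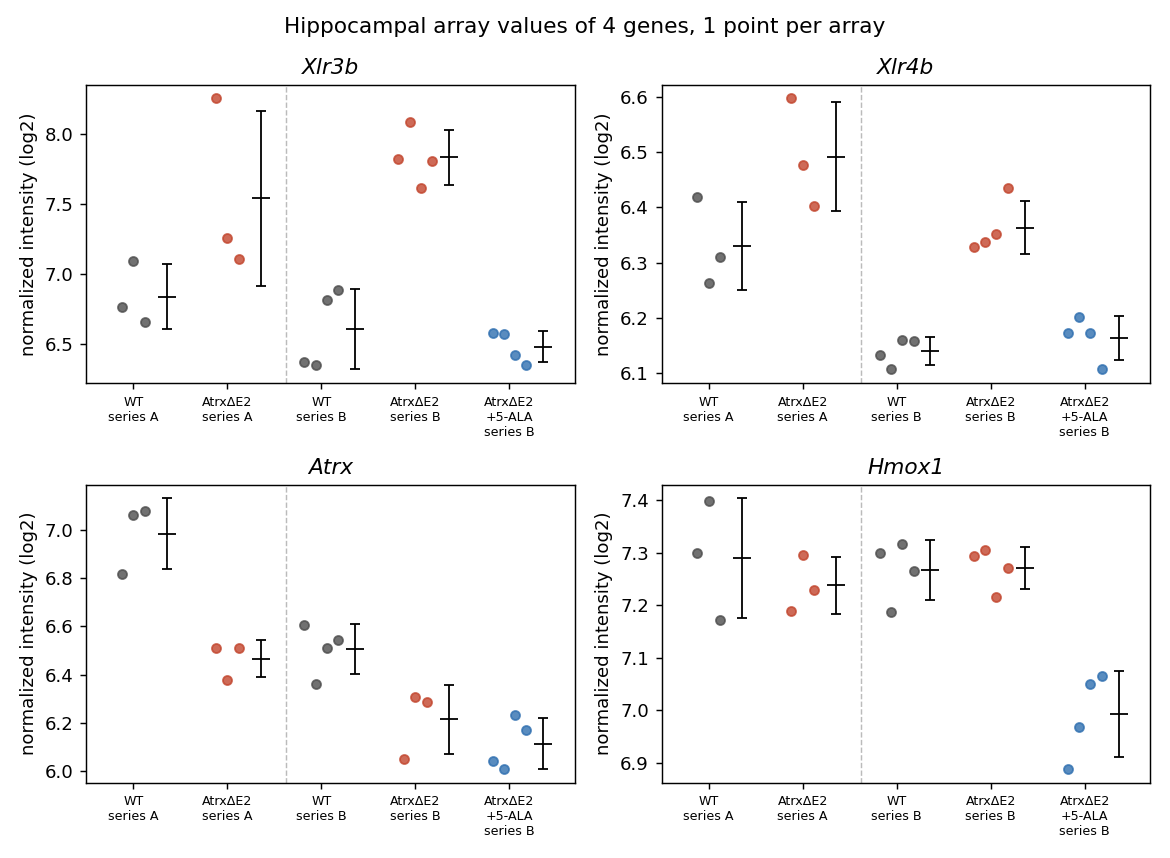
Normalized log2 intensity of Xlr3b, Xlr4b, Atrx and Hmox1, with 1 point per array by group and array series; bars give the mean and SD. In series B, Xlr3b averaged 7.83 in AtrxΔE2 and 6.48 after 5-ALA.

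Series A alone gave 0 limma calls for the genotype. Its 749 probes at an unadjusted p under 0.05 were fewer than 0.05 of the 22540 tested, the average share without any effect. Series B alone gave 451 calls, and 5300, most of them lower, were called when arrays were scaled to their median instead of quantile normalized. With consecutive arrays of series B averaged and series A left out, limma called 0 (1960 at an unadjusted p under 0.05). It called 1 with the level of the blank spots as a covariate. The count was 67 without wild-type 1, 13 and 12 without wild-type 4 and 5, and 99 and 11 without AtrxΔE2 3 and 6. The Xlr3b call was lost in 7 of 18 leave-one-out fits, those without wild-type 4, 5 or 6 or AtrxΔE2 4, 5, 6 or 7 (limma adjusted p up to 0.0821), and the Xlr4b call in 3, without wild-type 4 or 5 or AtrxΔE2 6 (up to 0.0602). The Atrx call was lost in 9, without wild-type 2, 3, 4, 6 or 7, AtrxΔE2 1, 2 or 4 or 5-ALA 4 (up to 0.106). Pisd, Akr1c14, Rit2, Slc22a4 and Tnfrsf17 lost theirs in 8, 12, 11, 10 and 15 fits (up to 0.123), while the calls of Plin3, S100a4, Prdm16, Cmtm8, Etnppl and Atp7a were kept in all 18.

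Of the 34 gene lists fixed beforehand, camera called 7 for the genotype. The choroid plexus and ependyma genes shifted up (median 0.23 over 19 measured genes, camera adjusted p 5.15e-12), with no member called over all genes and 13 higher when adjusted over the list alone; Clic6 (0.29), Calml4 (0.42), Sostdc1 (0.25) and Cldn2 (0.34) led. This list was the only one of the 7 still called with an estimated correlation, at an adjusted p of 0.0435. Its median was 0.05 in series A and 0.29 in series B. The same genes stood higher in series B than in series A, by a median of 1.78 in wild type and 2.14 in AtrxΔE2. The GABAergic interneuron genes shifted up (median 0.12 over 22 genes, camera adjusted p 0.0043; p 0.0133 with an estimated correlation, adjusted 0.151). Among them Slc32a1 stood at 0.30 and Penk at 0.55, and 3 members were higher when adjusted over the list alone against 0 over all genes. Penk also belongs to the list of neighbouring brain regions, including the striatum. Genes of the unfolded protein and heat shock response shifted down (median -0.06 over 25 genes, camera adjusted p 0.0043; p 0.00595 with an estimated correlation, adjusted 0.101). The chaperone gene Hsp90aa1 stood at -0.13 and the stress regulator gene Atf4 at -0.33 in that list, in which 0 members were called over all genes and 4 were lower when adjusted over the list alone. With arrays scaled to their median this list and the astrocyte list below turned upward (camera adjusted p 0.59 and 0.873).

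The other 4 genotype lists had no member called over all genes. Myelin genes shifted up (camera adjusted p 0.0223; p 0.304 with an estimated correlation), with a median of 0.23 in series A and -0.08 in series B. Astrocyte genes such as the connexin genes Gjb6 (-0.32) and Gja1 (-0.25) shifted down (camera adjusted p 0.0216; p 0.105 with an estimated correlation). Meningeal and fibroblast genes (camera adjusted p 0.0223; p 0.37 with an estimated correlation) and interferon and antigen presentation genes (camera adjusted p 0.028; p 0.24 with an estimated correlation) shifted down as well. Adjusted over the list alone, 3 myelin genes were higher, 1 astrocyte gene was lower and 0 meningeal or interferon genes were called. Leaving out single arrays ended these 4 calls: the myelin list without wild-type 2 or 3 or AtrxΔE2 1 or 2 (adjusted p up to 0.63), astrocytes without wild-type 3 or 7 or AtrxΔE2 2 or 7 (up to 0.149), meninges in 6 fits (up to 0.318) and interferon genes in 7 (up to 0.304). Not called were the list of the Xlr family and its X-linked neighbours (camera p 0.262), in which Xlr3b and Xlr4b rose, the imprinted genes (p 0.641, direction down, median 0.003) and the genes of the ancestral pseudoautosomal region (p 0.0288, adjusted 0.122). Nor was the list of neighbouring cortex, thalamus, septum and striatum (camera p 0.839), where 5 of 26 genes were higher and 7 lower when adjusted over the list alone.

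The treatment comparison asked what 5-ALA changed in AtrxΔE2 mice, and all of its 5-ALA arrays lay in series B. Atrx stood at -0.04 (SE 0.0832; 6 AtrxΔE2 and 4 5-ALA arrays) and was not called (limma adjusted p 0.83). Xlr3b fell by 1.24 (SE 0.208, 7 AtrxΔE2 and 4 5-ALA arrays, limma adjusted p 0.00308), to 0.238 of the untreated level on the authors' values, and Xlr4b fell by 0.19 (limma adjusted p 0.0104). Hmox1, which encodes the inducible enzyme of haem breakdown, fell by 0.27 (SE 0.0457, limma adjusted p 0.00377). Alas1, whose enzyme makes 5-ALA, stood at 0.05 (limma adjusted p 0.496), and Camk2a, a synaptic kinase gene, at 0.42 (limma adjusted p 0.0733), so neither was called. Xlr5d was at or below the 95th percentile of the blank spots on every 5-ALA array.

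Among the largest falls were Cap1, an actin regulator gene (-1.61, SE 0.371, limma adjusted p 0.0171), Plac9 (-1.38), Tmem254a (-1.19), the opioid precursor gene Penk (-0.95), Fbxo39, Srsf5, the polyamine enzyme gene Odc1 (-0.80), Cuedc1, the lysosomal protease gene Ctss (-0.75), the myelin gene Mbp (-0.75) and Cplx2, a vesicle release gene (-0.72). The synaptic vesicle gene Syp rose by 0.80 (SE 0.19, limma adjusted p 0.0201), followed by the activity-regulated transcription factor gene Egr1 (0.70), the phosphatase gene Ptpru (0.69), the postsynaptic scaffold gene Dlgap1 (0.63), the mitochondrial fusion gene Mfn2 (0.62), the neuronal glucose transporter gene Slc2a3 (0.62), Atp9a, Disp2, Hpcal4, Adcy2, Ncald and Galnt9. In all, limma called 1712 probes, 908 higher and 804 lower after 5-ALA, and 1298 of them carry a gene name. On the authors' values 493 were higher and 721 lower, so which direction held more calls depended on the processing. The median size of a called change was 0.26, and 92 calls exceeded 0.50. Within series B, consecutive arrays of a group resembled each other. With these pairs averaged and series A left out, limma called 0 probes (2527 at an unadjusted p under 0.05). Leaving out 5-ALA array 1 or 2 gave 700 and 740 calls, and without either array the calls of Syp, Cap1 and Mbp were lost (limma adjusted p up to 0.0822, 0.0539 and 0.0674), as was that of Penk without array 1 (0.0513); Egr1 and Atp9a lost their calls in 12 of 18 leave-one-out fits each (up to 0.151), Cplx2 in 8, Srsf5 and Ncald in 5 each, and Disp2 in 2. Of the 70 splits of the 8 series B arrays into 4 and 4, the real one gave the most calls (1710 among probes without an unusable spot), and the next, 1675, set 5-ALA 1 and 2 with AtrxΔE2 4 and 5 against the rest. The same division with the labels exchanged gave 209, the real one with the labels exchanged 393, and the other 2 splits that kept consecutive arrays together 1 and 5.

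Genes of glutamate receptors and the postsynaptic density shifted up after 5-ALA (median 0.11 over 31 genes, camera adjusted p 8.9e-05), and this call held with an estimated correlation (adjusted p 0.0315). Of these, 7 rose and 0 fell over all genes, and 9 rose when adjusted over the list alone; the AMPA receptor genes Gria2 (0.36) and Gria3 (0.39), the NMDA receptor gene Grin1 (0.44) and Dlgap1 were among them. CA1 pyramidal neuron genes shifted up (median 0.24 over 12 genes, camera adjusted p 0.00242) and also held with an estimated correlation (adjusted p 0.041). The 3 that rose, over all genes and when adjusted over the list alone, were Fibcd1 (0.35), Iyd (0.27) and Wfs1 (0.36), and Iyd and Wfs1 lost their calls in 6 and 10 leave-one-out fits. Iyd also belongs to the CA3 pyramidal list, which was not called (camera p 0.76), nor was the dentate granule list (camera p 0.17). Genes of ATRX partners and heterochromatin shifted up (median 0.11 over 25 genes, camera adjusted p 0.00366; p 0.0136 with an estimated correlation, adjusted 0.0867). There the DNA methyltransferase genes Dnmt1 (0.49) and Dnmt3a (0.11), the histone methyltransferase genes Setdb1 (0.28) and Ehmt2 (0.32), Suz12 and Morc3 rose, which makes 6 over all genes against 8 when adjusted over the list alone. The Dnmt3a call was lost in 16 leave-one-out fits (limma adjusted p up to 0.171), that of Morc3 in 6 and that of Suz12 without 5-ALA 1 (0.0808).

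Microglial genes shifted down (median -0.24 over 23 genes, camera adjusted p 2.08e-07; p 0.0153 with an estimated correlation, adjusted 0.0867). Of them 9 fell over all genes and 14 when adjusted over the list alone, with the complement genes C1qa (-0.50) and C1qc (-0.39), Ctss, Cd68 (-0.40) and Ly86 (-0.52) among the 9. Interferon and antigen presentation genes shifted down (median -0.13 over 22 genes, camera adjusted p 1.03e-06; p 0.0305 with an estimated correlation, adjusted 0.115, no longer called). The immunoproteasome gene Psmb8 (-0.63), Usp18, the MHC light chain gene B2m (-0.45) and the interferon regulator gene Irf7 were the 4 that fell over all genes, against 10 lower and 1 higher when adjusted over the list alone. In the haem biosynthesis list (camera adjusted p 0.00322; p 0.0107 with an estimated correlation, adjusted 0.0867) 6 of 18 genes fell over all genes and 7 when adjusted over the list alone. The 6 were Tspo (-0.39), a mitochondrial membrane protein gene, the pathway enzyme genes Alad (-0.40), Urod (-0.30), Ppox (-0.16) and Fech (-0.26), and Slc25a39 (-0.21). The median of the haem biosynthesis list was -0.112 in the fit of all arrays and -0.0667 on series B arrays alone. NRF2 target and oxidative stress genes shifted down (camera adjusted p 0.0138; p 0.0251 with an estimated correlation, adjusted 0.107, no longer called); Srxn1 (-0.46), Nqo1 (-0.20) and Gstp1 (-0.29) fell, 3 of 23 over all genes and also 3 when adjusted over the list alone. Calls lost without 5-ALA 1 or 2, or further arrays, were those of C1qc (limma adjusted p up to 0.0984), Irf7 (0.0753), Alad (0.0601), Urod (0.0628), Slc25a39 (0.11), Nqo1 (0.125) and Gstp1 (0.157). The haem breakdown and iron handling list, which holds Hmox1, was not called (camera p 0.297).

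Lists that mark myelin, the choroid plexus and neighbouring brain regions also shifted down, and these lists differed between the array series in wild type by 1.74, 1.78 and 0.42 (list medians, B minus A). The fit also used the AtrxΔE2 arrays of series A, where no 5-ALA array lay. On series B arrays alone the treatment medians were -0.211 for myelin, -0.315 for the choroid plexus and -0.000444 for neighbouring regions. Myelin genes (median -0.33 over 21 genes, camera adjusted p 2.83e-06; p 0.0833 with an estimated correlation) included 5 falls over all genes and 10 when adjusted over the list alone, among them Mbp, Gjb1 (-0.41), Qdpr (-0.47), Cryab (-0.64) and Aspa (-0.68). Choroid plexus genes (median -0.19 over 19 genes, camera adjusted p 1.03e-06; p 0.0116 with an estimated correlation, adjusted 0.0867, no longer called) included 5 falls over all genes and 10 when adjusted over the list alone, such as Sostdc1 (-0.61) and Folr1 (-0.52). In the model without the array series, the lists of oligodendrocytes and myelin, choroid plexus and ependyma, and neighbouring cortex, thalamus, septum and striatum turned upward (camera adjusted p 0.288, 0.0673 and 0.764), and so did Mbp (0.37), Sostdc1 (0.75), Folr1 (0.84) and Penk (0.30). Single arrays also ended calls of Qdpr (limma adjusted p up to 0.0501), Cryab (0.0973), Aspa (0.0963), Drd2 (0.0688) and Drd1 (0.15). In the list of neighbouring regions (camera adjusted p 0.0299; p 0.0645 with an estimated correlation) the median was -0.002 and the mean -0.14. The striatal genes Penk, Tac1 (-0.70), Rgs9 (-0.62), Drd2 (-0.26) and Drd1 (-0.57) fell, 5 of 26 genes over all genes against 9 lower and 1 higher when adjusted over the list alone. Endothelial and pericyte genes such as Cldn5 (-0.40) and Kcnj8 (-0.27) shifted down (camera adjusted p 0.0094; p 0.086 with an estimated correlation), with 4 of 23 genes falling over all genes and 5 when adjusted over the list alone. The endothelial list was no longer called without 5-ALA 3 or 4 (adjusted p up to 0.0682), nor the list of neighbouring regions without 5-ALA 3 (0.0548). Of 9 blood and erythroid genes (camera adjusted p 0.00242; p 0.0213 with an estimated correlation, adjusted 0.104, no longer called) Fech fell over all genes and 6 fell when adjusted over the list alone.

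**Figure D2:**
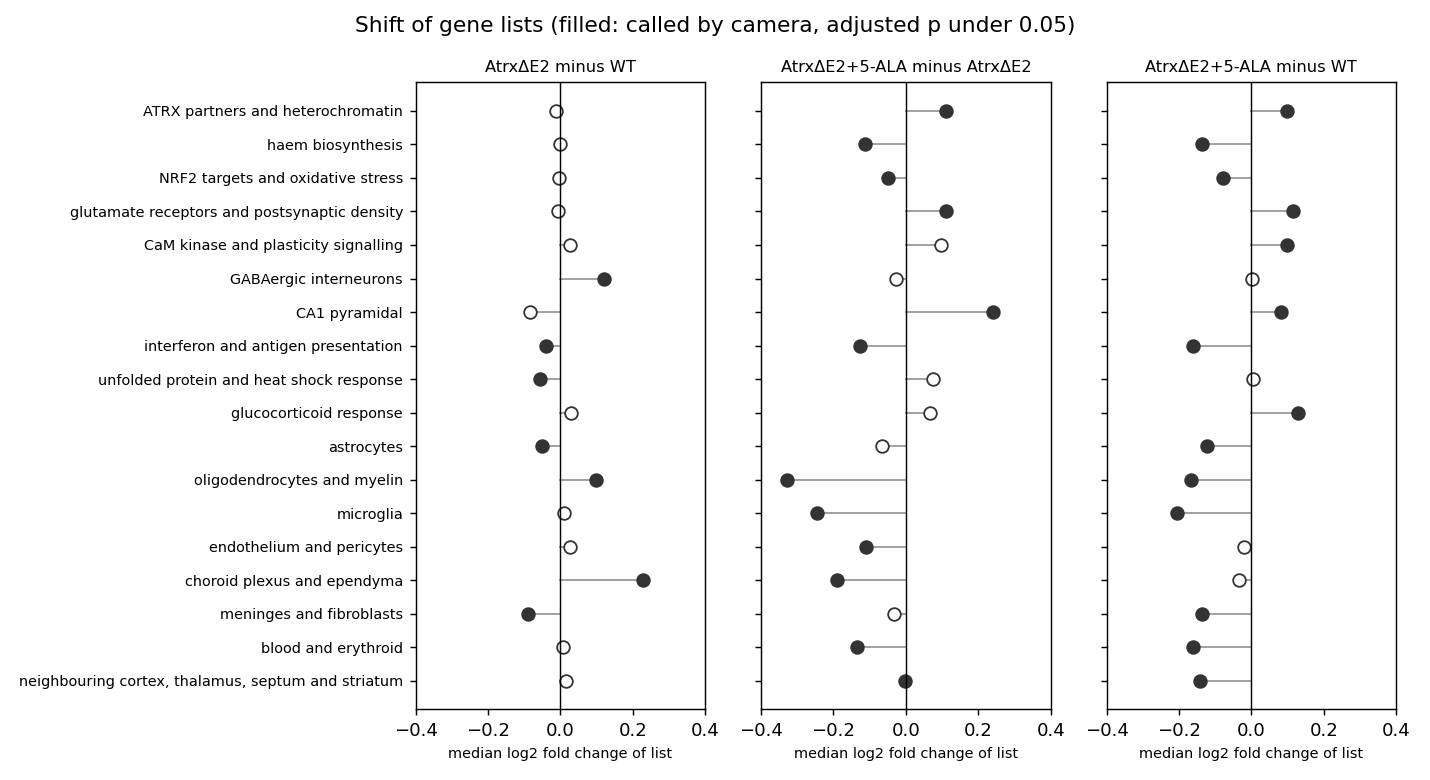
Median log2 fold change of the gene lists called in at least 1 comparison, by comparison; filled points mark lists with a camera adjusted p under 0.05. The microglia list stood at -0.24 after 5-ALA against AtrxΔE2 and at -0.20 against wild type.

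The third comparison asked what still separated 5-ALA-treated AtrxΔE2 mice from wild type. Atrx fell by 0.44 (SE 0.0794; 7 wild-type and 4 5-ALA arrays, limma adjusted p 0.00711). Xlr3b stood at -0.24 (SE 0.208, limma adjusted p 0.513) and Xlr4b at 0.01 (limma adjusted p 0.906), so neither was called. Camk2a rose by 0.52 (SE 0.139, limma adjusted p 0.0339), a call lost without wild-type 5, 6 or 7 or 5-ALA 1 or 2 (up to 0.127). The normalized log2 values were 9.72 and 9.80 on 5-ALA arrays 1 and 2 and 9.14 and 9.07 on arrays 3 and 4, against 8.77 to 9.12 in wild type of series B, and the rise was 0.19 without arrays 1 and 2 and was not called. Hmox1 fell by 0.29 (limma adjusted p 0.00329). The largest rises were Egr1 (1.07, SE 0.202, limma adjusted p 0.00747), the phospholipid flippase gene Atp8a1 (0.90), Spink8 (0.79), Cracdl, Tmem132a, Ski and Sult1c1 (0.66), and the largest falls were Plac9 (-1.20), Tmem254a (-1.11), Cuedc1 (-0.85), Psmb8 (-0.78) and the isoprenoid synthesis gene Idi1 (-0.76). In all, limma called 1719 probes, 912 higher and 807 lower than in wild type. On the authors' values 332 were higher and 1696 lower, and with arrays scaled to their median 846 and 278, so the balance depended on the processing. With consecutive arrays of series B averaged and series A left out, limma called 0 (3021 at an unadjusted p under 0.05). It called 0 with the level of the blank spots as a covariate (2194). Counts moved by more than 1.5 times without wild-type 4 (1134), 5 (1014), 6 (836) or 7 (874) and without 5-ALA 1 (648), 2 (517), 3 (2636) or 4 (2588), and the calls of Atp8a1, Cracdl, Tmem132a and Idi1 were lost in 2, 7, 3 and 6 leave-one-out fits (limma adjusted p up to 0.135).

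Camera called 14 lists here, and only the glutamate receptor and postsynaptic density list held with an estimated correlation (camera adjusted p 0.000153; 0.0319 with an estimated correlation). It held 10 genes that rose over all genes, against 12 when adjusted over the list alone, among them Gria2 (0.38), Gria3 (0.33), Grin2a (0.15) and Nlgn3 (0.16). The list of CaM kinase and plasticity genes shifted up (camera adjusted p 0.0284; p 0.0841 with an estimated correlation). Camk2a, Ppp1r9b (0.47), Prkca (0.28), Camk1g (0.34) and Itpka (0.41) rose, 5 over all genes against 6 higher and 1 lower when adjusted over the list alone. Glucocorticoid response genes shifted up (camera adjusted p 0.0163; p 0.0335 with an estimated correlation, adjusted 0.185), with Sgk1 (0.58), Per1 (0.50), Sult1a1 and Errfi1 rising and Gjb6 falling; adjusted over the list alone, 8 were higher and 1 lower. CA1 pyramidal genes (camera adjusted p 0.0382; p 0.0221 with an estimated correlation, adjusted 0.182) included Fibcd1 (0.46) and Lefty1 (0.43), which rose, 2 over all genes and 3 when adjusted over the list alone. Among ATRX partners and heterochromatin genes (camera adjusted p 0.0272; p 0.0397 with an estimated correlation, adjusted 0.185) Setdb1 (0.31), Dnmt1 (0.44) and Ehmt2 (0.28) rose and Atrx fell; adjusted over the list alone, 10 were higher and 3 lower. Leaving out single arrays ended the list calls of CaM kinase genes (without 5-ALA 3, adjusted p 0.0651), CA1 genes (without wild-type 7 or 5-ALA 3 or 4, up to 0.22) and ATRX partners (without 5-ALA 1, 0.0596). Of the 14 list calls, 11 were lost without both 5-ALA 3 and 4, and 3 without both 5-ALA 1 and 2. Gene calls lost without 5-ALA 1 or 2, or further arrays, were those of Ppp1r9b, Prkca, Camk1g, Itpka, Sgk1, Per1, Sult1a1, Errfi1, Gjb6, Lefty1 and Ehmt2 (limma adjusted p up to 0.165).

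Lower than in wild type after 5-ALA were interferon and antigen presentation genes (camera adjusted p 5.48e-09; p 0.0131 with an estimated correlation, adjusted 0.182), where B2m (-0.56), Usp18, Irf7, Psmb8, Psmb9 and Oas1a were among 8 that fell, against 13 when adjusted over the list alone. Microglial genes (camera adjusted p 3.24e-06; p 0.0268 with an estimated correlation, adjusted 0.182) held 10 falls over all genes and 12 when adjusted over the list alone, including C1qa (-0.53), C1qb (-0.50) and Ctss (-0.65). In the haem biosynthesis list (camera adjusted p 0.0128; p 0.0167 with an estimated correlation, adjusted 0.182) Ppox, Tspo (-0.29), Fech and Uros (-0.24) fell, 4 over all genes and 7 when adjusted over the list alone. Myelin genes (camera adjusted p 0.00265; p 0.209 with an estimated correlation) held 3 falls over all genes, Qdpr (-0.46), Aspa (-0.62) and Gjb1 (-0.21), and 9 lower and 1 higher when adjusted over the list alone. Of the blood and erythroid genes (camera adjusted p 0.0162; p 0.0434 with an estimated correlation, adjusted 0.185) Fech and Isg20 fell, and 5 were lower when adjusted over the list alone. In the list of neighbouring regions (camera adjusted p 0.0235; p 0.0497 with an estimated correlation, adjusted 0.188) Rora fell by 0.65, and 0 were called when adjusted over the list alone. Astrocyte genes (camera adjusted p 0.0235; p 0.138 with an estimated correlation) included Gjb6, which fell by 0.36, and the glutamate transporter gene Slc1a2, which rose by 0.33; adjusted over the list alone, 4 were lower and 2 higher. NRF2 target genes (camera adjusted p 0.0431; p 0.0553 with an estimated correlation) and meningeal genes (camera adjusted p 0.0356; p 0.436 with an estimated correlation) shifted down with 0 members called over all genes or when adjusted over the list alone. Single arrays ended the list calls of astrocytes (without 5-ALA 3 or 4, adjusted p up to 0.101), NRF2 targets (6 fits, up to 0.102) and meninges (7 fits, up to 0.203). They also ended the calls of Tspo, Fech, Uros, Qdpr, Aspa, Gjb1, Isg20, Rora and Slc1a2 (limma adjusted p up to 0.139). In the model without the array series, the myelin list turned upward (camera adjusted p 0.144).

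Whether 5-ALA moved transcripts against the genotype change was asked next. Xlr3b, Xlr4b, S100a4, Pisd, Etnppl and Atp7a were called in both comparisons with opposite signs: after 5-ALA S100a4 fell by 0.29, Pisd fell by 0.21, Etnppl rose by 0.41 and Atp7a rose by 0.09. The treatment calls of Pisd, Etnppl and Atp7a were lost in 12, 7 and 5 leave-one-out fits (limma adjusted p up to 0.148). Of the 20 genotype probes, 15 had the opposite sign in the treatment comparison, 10 of these were called there, and 0 were called with the same sign, where independent lists would share 0.741 with opposite signs. Both comparisons use the same AtrxΔE2 arrays, which alone forces opposite signs. In simulations without any effect, on average 17.8 of the 20 leading genotype probes had the opposite sign. The simulations called only 0.05 genotype and 0.08 treatment probes on average, too few to give a reference for the shared calls. The effects correlated at r = -0.277 across probes with shared arrays (simulated without effects -0.399), and their covariance was -0.00287 against a simulated -0.00152. When the AtrxΔE2 arrays of series B were split between the effects, r was 0.0569 with arrays 4 and 5 in the genotype effect and -0.12 with arrays 6 and 7 there.

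With no array shared, the genotype effect in series A and the treatment effect in series B correlated across 22540 probes at Pearson's r = -0.256 and Spearman's rho = -0.19. Probes are not independent replicates, so the labels were permuted within each series: 3 of 100 splits gave an r of this size (two-sided permutation p 0.03), and 12 of all 350 did (p 0.0343). These splits exchange single arrays, and of the 30 that kept the consecutive arrays of series B together 3 gave an r of this size (p 0.1, highest other 0.305), with only 3 divisions of series B among them. The permutation p passed 0.05 without wild-type 1 (r -0.156, p 0.22) or 2 (-0.212, 0.09), AtrxΔE2 1 (-0.206, 0.08), 3 (-0.148, 0.2) or 6 (-0.215, 0.06), or 5-ALA 2 (-0.239, 0.06), and equalled 0.05 without 5-ALA 1 (-0.255). On the authors' values r was -0.142 (p 0.05). The genotype effect of series A did not correlate with that of series B, which holds the 5-ALA arrays (r = 0.0242, two-sided permutation p 0.88). The r of -0.256 therefore does not show that 5-ALA opposed a genotype effect present in series B.

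Whether the genotype effect repeated between array series was the last question. Across 22540 probes, the AtrxΔE2 minus wild-type differences of series A and series B correlated at Pearson's r = 0.0242 and Spearman's rho = -0.00281 (two-sided permutation p 0.88, 100 splits). With arrays scaled to their median r was 0.319 (p 0.06). A limma interaction term called 23 probes whose genotype effect differed between the series, 12 with a higher value in series B and 11 with a lower one, and 0 of the 20 genotype calls were among them. The 20 were called from a fit of both series, which favours probes that move alike in both. This count of 0 is therefore no independent check that they repeat. Rora and Zic1, of the list of neighbouring brain regions, and Cldn2, of the choroid plexus list, were among the 23. Their series B minus series A differences were -1.03, -0.96 and 0.58 (limma adjusted p 0.0226, 0.0258 and 0.0129).

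The treatment and treated-against-wild-type comparisons called 978 probes in common, 977 of them in the same direction, where independent lists would share 65.5 in the same direction. They share the 5-ALA arrays, and the simulations without any effect, which called 0.08 probes in each on average, were too few in calls to give a reference for this overlap. The effects correlated at r = 0.843 across probes, and at 0.253 and 0.0957 when the 5-ALA arrays of series B were split between them. Genotype and treated-against-wild-type calls shared 10 probes, all in the same direction, with the wild-type arrays in common (0.781 for independent lists; the simulations again gave no reference).

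**Figure D3:**
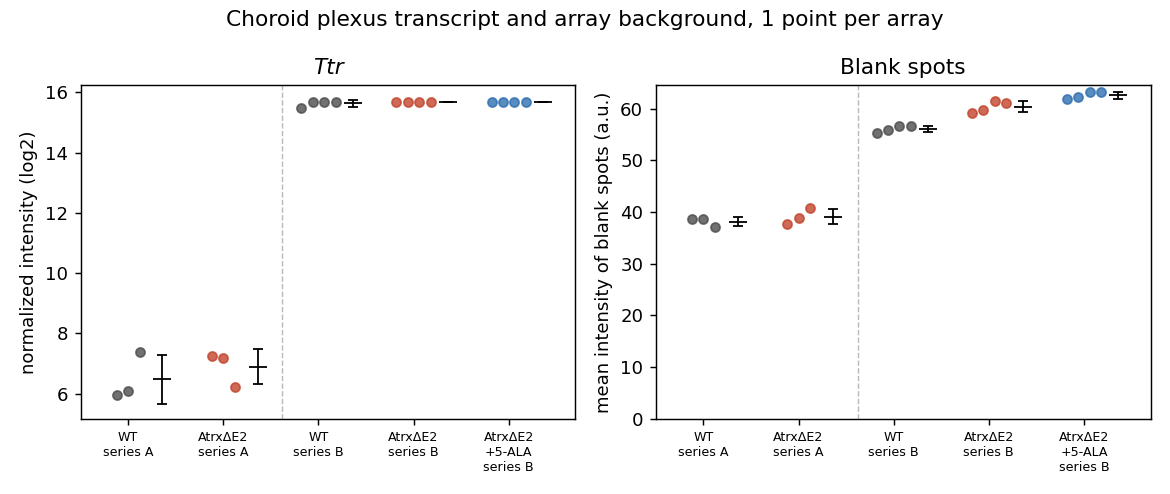
Normalized log2 intensity of the choroid plexus transcript Ttr (left) and mean intensity of the blank spots (right), with 1 point per array by group and array series; bars give the mean and SD. Blank spots averaged 38.1 units in wild type and 39.1 in AtrxΔE2 of series A, 56.1 in wild type and 60.4 in AtrxΔE2 of series B, and 62.6 on the 5-ALA arrays.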

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

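Chosen only after the result was seen were the tests of non-neuronal cells, of the processing order and of the genes beside Atrx, the fits without 5-ALA arrays 1 and 2 or with series B arrays in pairs, and the fit with the level of the blank spots.

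Single arrays lay far from the other 3 of their group (Dixon's test of 4 values, p under 0.05) in 15 of 505 groups of named genes, where chance gives about 1 in 20, or 25.2. The normalized log2 values of wild type in series B were 10.13 for Gsn (array 6), 6.608 for Lum (7), 10.72 for Disp2 (5), 9.933 for Hpcal4 (7) and 8.379 for Idi1 (5). In AtrxΔE2 of series B they were 8.719 for Odc1 (7), 10.87 for Gria2 (6), 9.815 for Gria3 (4) and 9.723 for Bpgm (6). Among the 5-ALA arrays they were 6.661 for Slc22a4 (3), 6.536 for Htr3a (4), 6.117 for Oas1a (4), 6.901 for Nqo1 (3), 7.907 for Wfs1 (3) and 6.798 for Slc1a2 (4).

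The genotype effect differed between the array series for 3 named genes (limma interaction term, series B minus series A): Cldn2 by 0.5827 (adjusted p 0.0129), Rora by -1.027 (0.0226) and Zic1 by -0.958 (0.0258).

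For the genotype, 1 of 100 splits of the arrays within the series (700 are possible), the real one, gave as many called probes: 18 among probes without an unusable spot, against at most 5 in the others. These splits exchange single arrays, while series B arrays resembled each other in pairs. The 12 other drawn splits that kept the pairs together also gave at most 5, but they are too few for a share under 0.05. With the pairs averaged and series A left out, limma called 0 probes (1960 at an unadjusted p under 0.05). For treated against wild type, the real split was the 1 of 70 with as many, 1711. The next, 1478, was the same division with the labels of the groups exchanged, and the 4 splits that mixed the groups in whole pairs gave 0, 0, 1 and 10. The splits that keep pairs together are too few for a share under 0.05. For the treatment, the real split was the 1 of 70 with as many called probes (1710), but the next, at 1675, set 5-ALA arrays 1 and 2 with AtrxΔE2 arrays 4 and 5 against the rest. That division gave 209 with the labels exchanged, the real one gave 393 with the labels exchanged, and the other 2 splits that kept pairs together gave 1 and 5, so the count depended on which arrays were called treated, and these splits are too few for a share under 0.05.

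The 5-ALA calls came with arrays that resembled each other in consecutive pairs. The astrocyte list lay 0.18 above the microglia list (permutation p 0.00085, genes exchanged between the lists). Genes of these lists were correlated (estimated at 0.128 and 0.201), so this p takes no account of the spread between mice. The astrocyte list also leaned down (median -0.07, 15 of 22 genes). A lower share of all non-neuronal cells stays open, since the test addresses only an equal fall of both lists. The lists that mark myelin, the choroid plexus and neighbouring brain regions shifted down after 5-ALA too. Whether the samples held unequal amounts of such tissue was not tested and stays open. A single unusual pair of treated arrays stays open: the effects of disjoint pairs correlated at only 0.0124 in 1 matching and at 0.373 in the other, and without 5-ALA arrays 1 and 2 limma called 329 probes. Background that rises along the arrays stays open too: 12.1% of the brightest probes were called and 1.68% of the dimmest, but quantile normalization and the offset leave few calls among dim probes whatever the source. With the level of the blank spots as a covariate, which rises with the groups, 559 probes were called for the treatment, 447 of them among the 1712, and 0 by limma against wild type (2194 at an unadjusted p under 0.05). The processing order cannot be told apart from the treatment, because every 5-ALA array had a higher blank level than every AtrxΔE2 array of series B, by at least 0.334 units. Nor can it be told apart from the genotype in series B, where blank levels were 55.2 to 56.6 in wild type and 59.2 to 61.4 in AtrxΔE2. The 5-ALA arrays, at 61.8 to 63.2, lay above all of these. In series A the genotypes overlapped (37.1 to 38.6 and 37.7 to 40.7).

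Choroid plexus genes were higher in series B than in series A on wild-type arrays, by a median of 1.69 (range 0.773 to 3.17) over 16 genes without Ttr, Enpp2 and Igf2. Of 10000 random lists of the same size and brightness 0 rose as much (highest median 0.377), which argues against a normalization or scanner difference as the source. Choroid plexus tissue in the series B samples may be the source, and the value of 1.69 was above the 1 that this needed. That value is the rise itself, on the same wild-type arrays, so it is no independent check of the tissue. It stays a hypothesis, since other differences between the series, such as litters or dissection days, are not described and were not tested.

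Atp7a, which lies beside Atrx on GRCm38.p6 with 2 measured genes between them, had the smallest genotype p. A stretch of chromosome carried along with the deleted allele may be the source. Of the 80 measured genes within 10 Mb of Atrx, 11.2% had an unadjusted p under 0.05, against 10.3% of 465 other X-linked genes (Fisher p 0.843), and Atp7a was the only one called over all probes. The test did not separate these shares, and a difference in a few genes would hardly move them, so an effect of the allele on Atp7a cannot be told apart from sequence differences next to it.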

How the results depend on the processing

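The fits with consecutive arrays of series B averaged or as a random block, without 5-ALA arrays 1 and 2 or 3 and 4, and with the level of the blank spots, and the permutations that keep pairs together, were chosen only after the result was seen. Of the values of named genes in the other alternatives, leaving out 1 array aside, 611 kept their side of the threshold for the genotype, called ones also their direction, and 61 lost a call; 852 and 270 did for the treatment and 941 and 182 for treated against wild type. Leaving out 1 array, 75, 201 and 167 lost a call and no called value turned direction; values near 0 that were not called, such as Alas1 for the genotype, crossed 0. Signal over background limits small folds of dim probes, and the self-test at 0.25 log2 recovered 76.1%, 67.2% and 55.2% of changed probes under independent noise, without the pairs seen in series B. The cause was not tested unless stated.

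Counts of called probes, in the order genotype, treatment and treated against wild type, were 20, 1712 and 1719. Without the array series they were 1 (929 at an unadjusted p under 0.05), 874 and 850. For the genotype, series B alone gave 451 and series A alone 0 by limma (749 at an unadjusted p under 0.05). With only the groups compared the treatment gave 695. Median scaling gave 5300 for the genotype, of which 4091 were lower, and 1124 for treated against wild type, 846 higher and 278 lower. The authors' values gave 493 higher and 721 lower for the treatment and 332 higher and 1696 lower for treated against wild type. The interquartile range of the log2 values was wider in AtrxΔE2 than in wild type of each series, 2.23 to 2.32 against 2.13 to 2.19 in series A and 1.77 to 1.92 against 1.66 to 1.72 in series B, a difference that quantile normalization removes and median scaling keeps. Cyclic loess gave 1085 for treated against wild type, a trended robust prior 43 for the genotype, and array weights 63 for the genotype and 1089 for the treatment. At an adjusted p under 0.1, the looser threshold itself, there were 46, 3107 and 3255, and at an unadjusted p under 0.05 with 1.5-fold 58 for the treatment and 52 for treated against wild type, since most called changes were smaller. Averaging consecutive arrays gave 0, 0 and 0 by limma (1960, 2527 and 3021 at an unadjusted p under 0.05). That fit left out series A and had fewer values per group, so it does not show what the pairing alone removed. Those pairs as a random block, with series A kept, gave 11, 544 and 314. Without 5-ALA arrays 1 and 2 the last 2 counts were 329 and 190, and without 3 and 4 they were 4391 and 4674. With the level of the blank spots they were 1 (782 at an unadjusted p under 0.05), 559 and 0 by limma (2194). The genotype counts of 749, 782 and 929 at an unadjusted p under 0.05 are each fewer than 0.05 of the 22540 tested probes, the average share without any effect. Leaving out 1 array gave 11 to 99, 700 to 2459 and 517 to 2636.

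A replicate block on the replicate numbers gave 9, 1 and 4 called probes (2048 and 2129 at an unadjusted p under 0.05 in the last 2) and 7 called lists for treated against wild type. The labels do not say that equal numbers mark a shared litter or day, and 2 of 14 wild-type and AtrxΔE2 arrays correlated best with their own number, so the numbers do not pair the arrays. Pisd turned to 0.02116 after treatment and the NRF2 list turned upward against wild type (adjusted p 0.86) in this replicate block.

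The correlation of the series A genotype effect with the series B treatment effect ranged from -0.313 to -0.148 leaving out 1 array. It was -0.256 with a permutation p of 0.1 when only permutations keeping consecutive arrays of series B together were counted, of which there are fewer. The permutation p was 0.05 with median scaling (-0.316), cyclic loess (-0.253) and the authors' values (-0.142). It was 0.22 without wild-type 1 (-0.156), 0.09 without wild-type 2 (-0.212), 0.08 without AtrxΔE2 1 (-0.206), 0.2 without AtrxΔE2 3 (-0.148), 0.06 without AtrxΔE2 6 (-0.215), 0.05 without 5-ALA 1 (-0.255) and 0.06 without 5-ALA 2 (-0.239). The correlation of the genotype effects of the array series ranged from -0.0937 to 0.0955 leaving out 1 array, and was 0.319 (p 0.06) with median scaling, 0.0497 with the authors' values and 0.00857 with cyclic loess.

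Called lists numbered 7, 12 and 14. With an estimated correlation there were 1, 2 and 1, and without the array series 4, 4 and 6. Without 5-ALA arrays 3 and 4 there were 3 for treated against wild type. Leaving out 1 array gave 3 to 7, 10 to 13 and 9 to 15; the genotype gave 3 without wild-type 3 or AtrxΔE2 2 and 4 without wild-type 2 or AtrxΔE2 7, and treated against wild type gave 9 without 5-ALA 3.

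Without the array series, which sets series B 5-ALA arrays against AtrxΔE2 arrays of both series, the treatment values turned upward for Penk (0.3048), Mbp (0.3703), Slc25a39 (0.04179), Gjb1 (0.02648), Qdpr (0.02411), Sostdc1 (0.7513), Otx2 (0.3242), Folr1 (0.8352), Kcne2 (0.6988), Cox8b (0.3201), Tac1 (0.2478), Rgs9 (0.3332) and Drd2 (0.2151), and against wild type for Qdpr (0.04268) and Gjb1 (0.2259). The lists of oligodendrocytes and myelin, choroid plexus and ependyma, and neighbouring cortex, thalamus, septum and striatum turned upward for the treatment (adjusted p 0.288, 0.0673 and 0.764), and myelin and choroid plexus against wild type (0.144 and 0.00868). For the genotype the myelin list turned downward in series B alone (0.597) and with averaged pairs (0.658). Median scaling turned the genotype lists of the mitochondrial respiratory chain (2.24e-06), the unfolded protein response (0.59) and astrocytes (0.873) upward. With the level of the blank spots, Rora (0.1803) and Aspa (0.1022) turned upward against wild type.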

Other observations

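Reported here are values noticed only after the result was seen, without an explanation.

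Between the array series, 12746 probes differed (limma adjusted p under 0.05), 5702 higher and 7044 lower in series B, and 287 of them by at least 2-fold. On wild-type arrays the myelin list was higher in series B by a median of 1.74 and the choroid plexus list by 1.78, the oligodendrocyte precursors by 0.13 and the list of neighbouring regions by 0.42.

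Root mean square differences within consecutive pairs of series B arrays were 0.1 to 0.125 in wild type, 0.109 to 0.117 in AtrxΔE2 and 0.116 to 0.12 after 5-ALA. Across pairs they were 0.116 to 0.144, 0.155 to 0.172 and 0.197 to 0.213. The nearest array was the partner for 3 of 4 wild-type arrays and for 4 of 4 in each other group. The labels do not mention pairs.

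Magt1 and Cox7b, which lie between Atrx and Atp7a on GRCm38.p6 and were looked up after the values were seen, stood at 0.19 (unadjusted p 0.000357) and -0.12 for the genotype and were not called.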
